A study of Mus musculus with 4 samples.

How the data were processed

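MicroRNAs (miRNAs) were measured in kidney RNA of 4 samples by quantitative PCR on TaqMan Low Density Assay v3.0 cards, microfluidic cards on which each well holds 1 preloaded assay. Per the labels, 2 samples came from kidneys pooled from 3 control mice and 2 from kidneys pooled from 6 female MRL/lpr mice. MRL/lpr is a mouse strain that carries a Fas mutation and develops lymphoproliferation and a lupus-like nephritis. The labels do not name the control strain, and the sample titles give a sex only for the MRL/lpr mice. The labels do not say whether the 2 samples of a group came from separate pools, so all p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, RNA was extracted with Trizol, 50 ng was reverse transcribed with Megaplex primer pools and preamplified, and 40 PCR cycles were run on an AbiPrism 7900 HT. Baseline and threshold settings are not given in the sources used here.

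Per the file headers, the deposited Ct table gives each sample's raw threshold cycle (Ct) in 768 numbered wells, with the sample's average U6 Ct beside it. A lower Ct means more template; 1 cycle was taken as a 2-fold difference, which assumes full PCR efficiency. U6 is a small nuclear RNA used as an endogenous control. The U6 average takes 1 value in the first 384 rows and another in the last 384, so these were treated as 2 cards. On each card it equalled the mean of 4 wells, which were treated as the U6 wells. The authors' deposited ratio is headed as the average of the MRL/lpr samples over the average of the controls. It was recomputed from the Ct table as the arithmetic mean of 2 to the power of minus (Ct minus U6 Ct) in each group. The recomputed ratio matched within 0.1% in 478 of the 480 wells that have one; the other 2 have no Ct in any sample.

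The files used here number the wells and do not pair the numbers with miRNA names, the reference table holds no well numbers, and the platform annotation of the cards was not used here. No well was therefore named, located in the genome or assigned a sequence. None of the 169 members of the 20 miRNA lists fixed before the data were examined (leukocyte, erythrocyte, endothelial, mesenchymal, tubular, epithelial and other-tissue markers, miRNA families and imprinted clusters) was matched to a row, and no list was tested. For the same reason miR-23b, fixed to be named in any case, has no value, and snoRNA controls were neither used as a reference nor removed from the tested wells.

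A well was tested when its Ct was under 35 in all 4 samples, which left 425 wells, 237 on the first card and 188 on the second. The U6 wells were left out. The normalized level is minus the difference between a well's Ct and the sample's mean Ct over the tested wells of the same card. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the 425 wells, threshold 0.05), with all 4 samples in 1 fit and no covariate. An exact permutation test of 2 against 2 samples cannot give a two-sided p under 0.333, so none is reported. Wells with a Ct under 35 in both samples of one group and in neither of the other were counted apart. Their fold is a lower bound, relative to the card mean, that places the other group at Ct 35. The rule for named wells took 10 per direction past the threshold, filled with the largest log2 fold changes of at least 1 whose groups did not overlap. Because the wells are not named here, only the first 2 per direction are given.

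The script was tested on simulated data: 50 data sets of the 425 wells, with variances drawn from the fitted prior and 20 wells changed at each of 3 sizes. The main model recovered 2.3% of wells changed by 1 on the log2 scale, 42.7% of those changed by 2 and 86.3% of those changed by 4, with a mean of 1.08 false calls per data set. The simulated variances did not depend on Ct, whereas the replicate spread of the data grew with it. These rates therefore do not describe early or late wells separately. Noise was also drawn independently for each well, and the rates depend on how many wells were changed and by how much. They may not hold for these data. Alternatives, chosen before the data were examined unless stated, were other references (U6, quantile, median, none), Ct limits of 32 and 38, undetermined wells set to Ct 40, a replicate block, other variance priors and leaving out each sample. References within blocks of 48 wells, combinations with the variance prior that follows the mean level, limits moved by each sample's mean Ct and geometric means of the ratios were chosen after seeing the data. No column of per-sample values was left unused. Figures were drawn with matplotlib 3.10.9.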

Results

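The series compared miRNA levels in kidneys of lupus-prone MRL/lpr mice with those of control mice, with 2 samples per group. Each sample was read on 2 cards of 384 wells. In control replicates 1 and 2, 563 and 527 of the 768 wells gave a Ct, and 510 and 478 gave a Ct under 35. In MRL/lpr replicates 1 and 2, 523 and 533 wells gave a Ct, and 462 and 486 gave a Ct under 35. Ct values ran from 12.21 to 39.96 over all samples. Leaving out the U6 wells, 425 wells had a Ct under 35 in all 4 samples, 112 had one in 1 to 3 samples, and 223 had one in none. The tables used here number the wells without miRNA names, and the platform annotation was not used here, so each well is referred to by its number. Control RNAs other than U6 were not removed, so a given well need not hold a miRNA.

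U6 RNA, the endogenous control on the cards, came up later in both MRL/lpr samples than in either control; this was not tested. On the first card its Ct was 14.38 ± 0.46 in control and 15.01 ± 0.02 in MRL/lpr kidney (SD, n = 2). On the second card it was 14.67 ± 0.56 in control and 15.15 ± 0.02 in MRL/lpr kidney (SD, n = 2). There control replicate 2, at 15.07 cycles, lay close to MRL/lpr replicates 1 and 2, at 15.16 and 15.14. The SD over the U6 wells of that control was 0.069 cycles, so this separation was about as small as well noise. Each control SD is the spread between the 2 replicates, at 14.05 and 14.70 cycles on the first card and 14.27 and 15.07 on the second. The 4 U6 wells of 1 card differed by much less than the control replicates, with an SD between 0.02 and 0.149 cycles. The mean Ct of the tested wells averaged 0.82 cycles higher in MRL/lpr kidney on the first card and 0.58 on the second. Control replicate 1 had the lowest mean Ct on both cards (23.34 and 25.92), and on the second card the groups overlapped, with 27.27 in control replicate 2 and 26.91 in MRL/lpr replicate 2. Without a reference, the median well was therefore lower in MRL/lpr kidney by a log2 fold change of -0.78; relative to U6 this median was -0.21, and relative to the card mean -0.06.

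After normalization to the card mean, profiles were close in all sample pairs. Across wells, Pearson's r was 0.976 between the control samples, 0.980 between the MRL/lpr samples and 0.965 to 0.973 between samples of different groups; wells are not independent replicates. The median absolute difference between replicates was 0.43 on the log2 scale in control and 0.33 in MRL/lpr kidney, and between samples of different groups it was 0.43 to 0.57. It grew with Ct: among wells with a mean Ct under 21 it was 0.29 in control and 0.17 in MRL/lpr, and among wells with a mean Ct of 30 or more it was 0.87 and 0.61. The 2 samples of a group hold different values and were counted as 2 samples; whether they came from separate pools is not known.

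Most tested wells differed little between MRL/lpr and control kidney: 352 of 425 (82.8%) had a fold change under 2. Of the other 73 wells, 44 were higher and 29 were lower in MRL/lpr kidney, and in 63 of the 73 the samples of the groups did not overlap. Picking wells by fold change makes such separation more likely. Relative to U6 the balance turned, with 36 wells at least 2-fold higher and 48 at least 2-fold lower, so that the share of higher wells went from 60.3% to 42.9%. No well passed limma's test after Benjamini-Hochberg adjustment, in either direction; the smallest adjusted p was 0.158. At an unadjusted p under 0.05, 67 wells passed (33 higher and 34 lower), where 21.2 would be expected by chance. The groups did not overlap in 190 wells (44.7%), against 33.3% expected by chance for 2 samples against 2. Some of the 3 ways to split the 4 samples would exceed 33.3% even without a group difference. All wells share the same samples, so neither this excess nor that of the 67 wells has a known error. The other ways to split the samples gave 13 wells each at an unadjusted limma p under 0.05. In those fits a real group difference would add to the residual spread and lower the count. The 13 are therefore no chance level for the 67. The 95% confidence interval of a typical well reached 1.91-fold to either side (median half-width 0.94 on the log2 scale, n = 2 per group).

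The largest fold changes among wells whose groups did not overlap were in wells with late Ct. Well 130, on the first card, was 15.2-fold higher in MRL/lpr kidney (log2 fold change 3.93 ± 1.22, SE; limma adjusted p = 0.27). Its Ct was 30.75 and 30.48 in the controls and 26.13 and 28.88 in MRL/lpr, so that much of its size came from replicate 1; without that sample its log2 fold change was 2.27. Well 685, on the second card, was 10.8-fold higher (3.43 ± 0.44, SE; limma adjusted p = 0.158), with a normalized level of -4.14 ± 0.74 in control and -0.71 ± 0.11 in MRL/lpr kidney (SD, n = 2). Among lower wells, well 300 on the first card was 51.0-fold lower (log2 fold change -5.67 ± 1.34, SE; limma adjusted p = 0.254). Its Ct was 26.88 and 25.84 in the controls and 31.45 and 34.25 in MRL/lpr, and its log2 fold change ran from -7.35 to -4 when single samples were left out. Well 556 on the second card was 8.83-fold lower (log2 fold change -3.14 ± 0.39, SE; limma adjusted p = 0.158), with MRL/lpr Ct values of 34.99 and 34.95, just under the detection limit. None of these 4 wells passed the adjusted threshold with the card mean as reference and the main model.

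**Figure D1:**
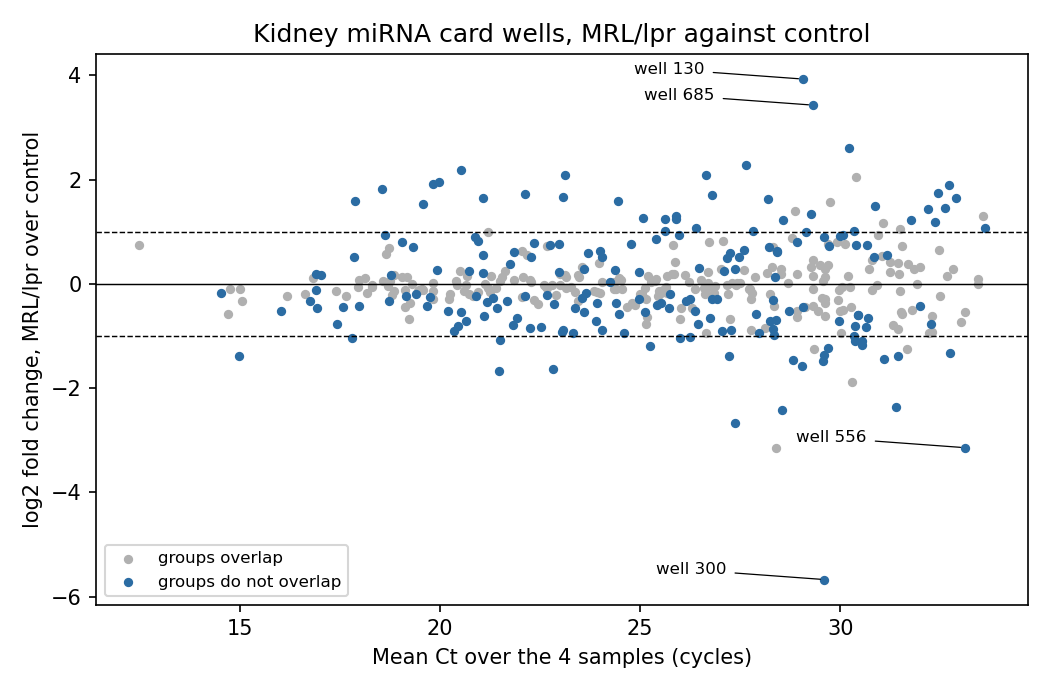
Log2 fold change (MRL/lpr over control, relative to the card mean) of the 425 tested wells against their mean Ct in cycles; each point is a well, blue where the samples of the groups do not overlap, and dashed lines mark a 2-fold change. Fold changes of at least 2 make up 10.8% of the 251 wells with a mean Ct under 27 and 26.4% of the 174 wells with a later one.

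**Figure D2:**
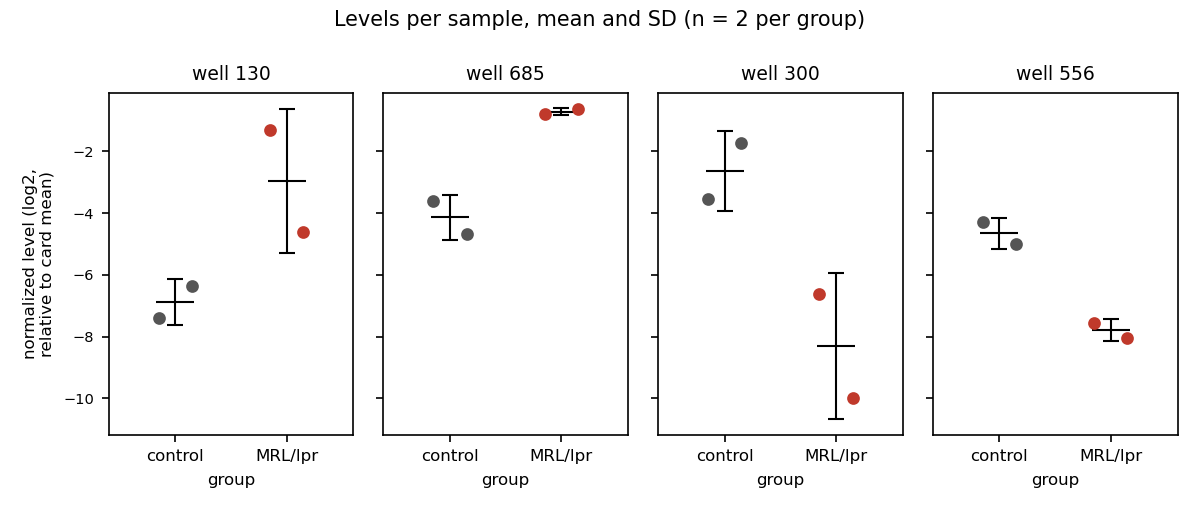
Normalized level (log2, relative to the card mean) of the 4 named wells; points are samples, and the horizontal mark and bar give the mean and SD (n = 2 per group). The groups do not overlap in any of the 4 wells, as the rule for named wells required, and the MRL/lpr samples of wells 130 and 300 lie far apart (SD 2.34 and 2.37).

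The outcome of the test depended on how the variance was modelled. When the prior variance was allowed to follow the mean level, 8 wells passed limma's adjusted threshold, 6 higher (2.89- to 10.8-fold) and 2 lower (3.10- and 3.19-fold) in MRL/lpr kidney, with adjusted p from 0.00601 to 0.0338. Of these 8 wells, 7 had a mean Ct between 18.6 and 22.8. Well 685 was one of the 8 (limma adjusted p = 0.0278), and wells 130, 300 and 556 were not. The same model relative to U6, chosen after seeing the data, called 17 wells, with 7 of the 8 among them; wells 130, 300 and 685 passed there (limma adjusted p = 0.00373, 1.91e-06 and 0.00577) and well 556 did not (0.0834). With 1 sample left out, a fit chosen after seeing the data, 1 residual degree of freedom remained, and the lone sample was assumed to vary like the other group. No well then passed without MRL/lpr replicate 1 or 2, where the controls alone supplied the spread. Without control replicate 1 or 2, where the MRL/lpr samples alone supplied it, 13 and 26 wells passed, with 7 and 8 of the original 8 among them. In each of these 4 fits all 8 wells kept a fold change of at least 2 in the same direction, the smallest being 2.33-fold. The samples of the groups did not overlap in any of the 8, so leaving out 1 sample could hardly reverse a direction. The 8 were also picked from the same data, so this is no independent support.

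Some wells gave a Ct under 35 in one group only. Both control samples and neither MRL/lpr sample did so in 9 wells, at least 1.13- to 64.1-fold higher in control when the other group was placed at Ct 35. Both MRL/lpr samples and neither control sample did so in 3 wells, at least 3.24- to 5.49-fold higher in MRL/lpr. The bounds are relative to the card mean and depend on it. Its later Ct in MRL/lpr kidney raises the bounds for MRL/lpr and lowers those for control. Each bound uses the mean of the 2 detected samples, which could lie far apart. The 5.49-fold well read 31.89 and 34.83 cycles in MRL/lpr, and the 1.13-fold well 33.48 and 34.99 in control. In 3 of the 9 and 1 of the 3 wells the other group was undetermined in both samples. The other ways to split the 4 samples into pairs gave 7 and 9 such wells, against 12 for the real groups. These wells were not tested.

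In the authors' deposited table, 48 of 480 wells had a ratio of at least 2 and 77 a ratio of 0.5 or less; 2 of the 77 had no Ct in any sample. These ratios are relative to U6, and the table gives no test. The samples of the groups did not overlap in 34 of the 48 wells, and in 48 of the 75 lower wells that had a Ct in every sample. Here too, picking wells by their ratio makes such separation more likely. At least 1 sample had a Ct of 35 or later in 12 of the 48, and in 20 of the 75. The highest ratio in the authors' deposited table, 43.1, came from a well with Ct 38.5 to 39.8 in control and 33.4 to 34.4 in MRL/lpr. The lowest, 0.00601, came from a well whose control samples read 28.9 and 34.8 cycles and whose MRL/lpr samples read 37.5 and 39.4. The authors' deposited table gives ratios of 18.8, 8.92, 0.022 and 0.0961 for wells 130, 685, 300 and 556. Over the 425 tested wells, the ranks of the deposited ratios and of the fitted fold changes had a Spearman's rho of 0.968, from the same Ct values.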

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

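With 17 alternatives, 14 planned and 3 (blocks of 48 wells and 2 combinations with the trend model) added after seeing the data, no well higher in MRL/lpr kidney passed in 14, and no lower one in 13. With the prior variance following the mean level, 6 higher and 2 lower wells passed; with U6 as reference as well 10 and 7, and with a replicate block as well 17 and 12. The trend model gave 0 to 26 calls with single samples left out (also added after seeing the data), 0 without either MRL/lpr sample, when only the controls supply the spread. Without normalization 1 lower well passed, and 16 wells were at least 2-fold higher and 142 at least 2-fold lower, in place of 44 and 29. At least 2-fold lower wells numbered 48 relative to U6, 51 with undetermined wells at Ct 40, where 469 wells are tested, and 36 to 49 without single samples. A Ct limit of 32 left 5 in place of 9 wells detected only in control. The named wells were picked for large fold changes without overlap between the groups. Leaving out 1 sample could therefore hardly reverse them, and another variance prior or a replicate block does not alter a fold change. They kept their direction in every alternative run: wells 130 and 685 in 17, wells 300 and 556 in 16, since a Ct limit of 32 removes both. Their adjusted p ranged from 0.00373 to 0.592, 0.00107 to 0.592, 1.91e-06 to 0.592 and 0.0335 to 0.592. The replicate block alone gave 0 calls. After normalization to the card mean, the deviations of same-numbered samples had r = -0.036 across wells, so no pairing by number was seen there. That normalization removes shifts common to a card, and each group has 1 sample of each number. A batch shared by same-numbered samples therefore cannot be excluded. For all other changes the cause was not tested. The snoRNA reference and the list tests were not run, because the wells are not named here. Replicate spread, larger in late than in early wells in both groups, limits late wells most.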

Other observations

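All tests in this part were chosen after the data had been examined; for loading ports and late wells the predictions were written before the result of the test was seen.

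Of the 73 wells with a fold change of at least 2 between the groups, 46 had a mean Ct of 27 or more, where replicates differed most. Noise of wells with a late Ct as the whole cause was tested on the 251 earlier wells. The real groups gave 27 wells with a fold change of at least 2 there (exact 95% Poisson interval 17.8 to 39.3). The other splits of the samples gave 12 and 10, below that interval. That 27 of the 73 wells were early ones is a plain count, which would hold whatever the other splits gave. The interval treats wells of the same 4 samples as independent, and only 3 splits exist. The test thus cannot decide whether the 27 exceed noise. A card is filled through ports that each feed 48 wells, so loading could shift blocks of wells. With the reference taken within blocks of 48 consecutive wells, 67 of the 73 kept a fold change of at least 2 (exact 95% binomial interval 83% to 96.9%). This argues against loading ports as the cause, although that interval too treats wells as independent. The 4 samples can be split in only 3 ways, too few for a share under 0.05: the real split gave 73 wells, the highest of the others 50, so 1 of the 3 splits gave as many. A strain difference, a sex difference, the disease, or a difference between single pools remains open and was not tested.

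Control replicate 1 alone had a Ct under 35 in 30 wells, against 9, 4 and 9 wells for control replicate 2 and MRL/lpr replicates 1 and 2. Its mean Ct was also the lowest, by 0.80 and 0.96 cycles below the mean of the 4 samples on the first and second card. More template in control replicate 1 may account for this: with each sample's limit moved by its own mean Ct, its wells fell to 18, against 6, 8 and 11. Those 18 were 41.9% of the 43 wells, against 25% for an equal share (two-sided exact binomial p = 0.081 after multiplying by 4, since the sample was picked as the highest of 4). That p also treats wells as independent, so whether more template accounts for the whole excess stays open. No biological explanation was tested, since the labels do not set this sample apart from the other control.

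The authors' deposited table lists ratios of 0.342 and 0.0297 for wells 767 and 768, the last of the second card, although all 4 samples are undetermined there. It lists no ratio for 123 wells that gave a Ct in 1 to 3 samples. Because that table averages 2 to the power of minus (Ct minus U6 Ct), the sample with the earlier Ct weighs most: in 22 of 478 wells a geometric mean, chosen after seeing the data, falls on the other side of 1. With it, 50 wells have a ratio of at least 2 and 65 a ratio of 0.5 or less, against 48 and 75.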
